A study of Mus musculus with 3 samples.

How the data were processed

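The deposited matrices hold UMI counts, which, per the file headers and the extract protocol, the authors made with Cell Ranger 3.0.2 and the 10x mm10 reference. The processing notes of the authors also name Seurat 3.1.1, without saying what it was used for. Every deposited barcode has at least 500 UMIs, and the filter behind this is not stated. The values were whole counts for 31053 genes in each of 3 libraries. Alignment was not repeated, since no reads were available.

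Cells with at least 200 detected genes and at most 20% of UMIs from mitochondrial genes were kept, which removed 12 neural stem cells, 7 astrocytes and 13 MIM-treated astrocytes. Median genes per cell were 653, 1835 and 1266.5 in that order. Mitochondrial genes took 1.46%, 1.80% and 2.10% of UMIs, and Malat1 took 26.9%, 13.7% and 9.44%. Scrublet, as implemented in scanpy, called 0 cells in each library. That call is unlikely to be right for droplet libraries of this size, so doublets were kept. An alternative left out the 8% of cells of each library with the highest Scrublet score.

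UMIs were summed over the kept cells of a library and divided by the library total. Log2 ratios used a pseudocount of 1 CPM. A gene counted as higher or lower when its log2 ratio was at least 1 in size and it reached 50 CPM in either library. Fold differences are ratios of CPM without the pseudocount, with exact 95% intervals for counts. Where 1 library had 0 counts, the fold is a lower bound against a floor of 3 counts, which leaves out the counting error of the other library. The 13 genes with the largest log2 ratio in each direction under this rule were named for each comparison, leaving out mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and gene models with clone-like or accession-like names. This rule was fixed before the data were examined. Gfap, Nes, Sox2 and Mki67 were among the markers fixed beforehand, and other genes are examples from the gene lists, picked mostly by size of log2 ratio after the values were seen. Coordinates came from GENCODE vM21, matched by gene ID for 66 of 66 named genes.

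There were 30 gene lists fixed before the data were examined. A member was measured when both libraries together held at least 20 UMIs. List medians were set against 10000 random lists matched on mean expression rank within a window of 100 genes. Where the sign of a list median differed between library totals, TMM, totals without mitochondrial and ribosomal protein genes, and totals without Malat1, this is said beside it.

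The share of genes toward neural stem cells and the slope both use the astrocyte library in each difference. Both were set beside 100 simulations with no effect, beside values with astrocyte cells split at random between both differences, and, chosen after seeing the data, beside 100 sets of profiles with shuffled genes. Slope and correlation intervals came from 1000 bootstraps over genes.

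Cells were thinned to 1000 UMIs without replacement, with 2000 as an alternative. Reference profiles came from a random 50% of neural stem cells and of astrocytes, and the remaining cells were scored with Pearson correlation across 3319 genes. Clustering scaled cells to 10000 UMIs, took 2000 variable genes, 30 principal components and 15 neighbours, and used the Leiden method at resolution 0.5. No integration was applied, because each library is a separate group. By a rule chosen after seeing the data, a cluster was named when at least 3 markers of 1 class stood among its top 50 genes, ranked with a pseudocount of 10 CPM.

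A self-test simulated counts with known differences in 50 genes per fold. At 3-fold and 4-fold 100% were called in every comparison. At 2-fold, which is the size rule itself, 48%, 50% and 56% were called. At 1.5-fold at most 6% were called, and 0 unchanged genes were called. The simulated counts held counting error only, so these calls say nothing of variation between cultures of the same kind. Simulated slopes of 0, 0.3 and 0.6 were recovered as 0.00100, 0.299 and 0.601.

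Alternatives fixed before the data were examined changed the cell filters, scaling, pseudocount, expression threshold, depth, correlation and cluster resolution. Others, chosen after seeing the data, left Malat1 out of the totals, left out the cells with the highest Scrublet scores, and left out shallow clusters with out-of-place cells. The random seed was 1. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.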

Results

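Gene expression in single cells was measured in 3 mouse cortical cultures with 10x Genomics libraries made from methanol-fixed cells. Each of the 3 groups was 1 library. Neural stem cells were grown as neurospheres from embryonic cortex at E14.5, in serum-free medium with EGF and FGF2. Astrocytes were kept in a differentiation medium with 10% serum. MIM-treated astrocytes had been moved from that medium to MIM, a serum-free medium with FGF2 at 20 ng/mL and a combination of cysteine, glycine, methionine, putrescine, S-adenosylmethionine and threonine. They were collected at or before day 5. The labels give neither the combination nor the day used for this library, and do not say whether the astrocytes came from postnatal cortex or from neurospheres. They give E14.5 for the astrocyte samples too, which does not match the postnatal source that the protocol describes. The treated and untreated astrocytes thus differed in serum, FGF2, base medium and metabolites together, and no comparison here separates the metabolites from the rest of the medium.

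The neural stem cell library held 14696853 UMIs in 9157 barcodes, the astrocyte library 50598967 in 9825, and the MIM-treated library 50915129 in 14977. After filtering, 9145, 9818 and 14964 cells remained, with medians of 1379, 5089 and 3156 UMIs per cell. Levels are UMIs summed over the cells of a library and scaled to its total (CPM). There are no replicates, so no difference below has a replicate check or a test. Intervals of levels, folds and shares of cells are exact 95% intervals that cover counting error only. Those of shares of genes, medians over genes, slopes and correlations across genes treat genes as independent, which they are not. A gene is counted as higher or lower in a comparison where its log2 ratio (pseudocount 1 CPM) was at least 1 in size and its level at least 50 CPM in either library. Members of a gene list are counted by the log2 ratio alone. Each list's median is placed by its percentile among 10000 random lists of the same size and matched mean expression.

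The first comparison asked how astrocytes kept in MIM differed from astrocytes left in their own medium. Cell division genes were far higher in MIM-treated astrocytes. Prc1, which bundles microtubules at the midzone of dividing cells, stood at 704 CPM (697 to 711) against 0.810 CPM (0.582 to 1.10), a ratio of 869-fold (640.2 to 1211). Some astrocyte markers were lower. Gfap, the astrocyte intermediate filament, stood at 4.05 CPM (3.51 to 4.64) against 272 CPM (267 to 276), 67.1-fold lower (58.5 to 77.4). Aqp4, the water channel of astrocyte endfeet, was 24.7-fold lower (23.3 to 26.2). In all, 426 genes were higher and 508 lower among 2895 at 50 CPM or more. With TMM scaling, which moved the median log2 ratio of all these genes up by 0.24, the split was 611 higher and 381 lower, 61.6% higher against 45.6% with library totals.

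The 13 genes with the largest positive log2 ratio in MIM-treated astrocytes were Prc1, Pclaf, Ube2c, Ccnb2, Pbk, Birc5, Cenpf, Ckap2l, Hmmr, Top2a, Cdca8, Cdca3 and Tk1, which act in DNA replication, chromosome segregation or mitotic exit. Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, had 3 UMIs in astrocytes and 15704 in MIM-treated astrocytes, a ratio of 5203-fold with a counting interval from 1779.9 to 25230.4. Top2a, the topoisomerase that untangles replicated DNA, was 143-fold higher (108 to 195). Mki67, the proliferation marker, had 0 UMIs in astrocytes and 18.1 CPM (16.9 to 19.3) in MIM-treated astrocytes, at least 305-fold higher against a floor of 3 counts. Of 42 measured S phase genes 33 were higher and 0 lower, with a median log2 ratio of 2.06 at percentile 100. Of 52 measured G2 and M phase genes 47 were higher and 0 lower, with a median of 3.44 at percentile 100. With a pseudocount of 10 CPM these medians were 0.80 and 1.43, and only 8 S phase and 21 G2 and M phase genes also reached 50 CPM. Prc1 (ENSMUSG00000038943) lies on mm10 chromosome 7 at 80294450 to 80316259 and Top2a (ENSMUSG00000020914) on chromosome 11 at 98992943 to 99024189. Gfap (ENSMUSG00000020932) lies on chromosome 11 at 102887336 to 102900912.

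The 13 genes with the largest negative log2 ratio were Serpinf1, Lbp, Elobl, Hspb8, Ass1, Wisp2, Cidea, Defb1, Pth1r, Omd, Gfap, Cnmd and Tagln. Serpinf1, a secreted neurotrophic and anti-angiogenic serpin, was 411-fold lower (345 to 493) at 2.48 CPM in MIM-treated astrocytes against 1016 CPM in astrocytes. Hspb8, a small heat shock protein, was 106-fold lower (98.1 to 116). Defb1, an antimicrobial defensin, had 0 UMIs in MIM-treated astrocytes and 2895 in astrocytes, at least 971-fold lower against the same floor. Tagln, an actin-binding protein of contractile cells, was 54.5-fold lower (47.9 to 62.3).

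Inflammatory and contractile genes were lower as groups in MIM-treated astrocytes, many of them at low levels. Of the lower genes below, only 5 interferon response, 5 reactive astrocyte and 2 contractile and serum response genes also reached 50 CPM. Of 20 interferon response genes 18 were lower and 0 higher, with a median log2 ratio of −2.23 at percentile 0. Isg15, a ubiquitin-like antiviral protein, was 11.8-fold lower (10.6 to 13.2), and Ifit1, which binds viral RNA, had a log2 ratio of −4.39. Of 21 reactive astrocyte genes 13 were lower and 0 higher, with a median of −1.47 at percentile 0. Complement C3 was 80.5-fold lower (61.9 to 107), and the small heat shock protein gene Hspb1 was 47.4-fold lower (39.6 to 57.2). Of 18 contractile and serum response genes 10 were lower and 0 higher, with a median of −1.44 at percentile 0. Smooth muscle actin, Acta2, was 137-fold lower (84.0 to 239.5). Thbs1, an adhesive matrix glycoprotein induced by serum, had a log2 ratio of −4.94.

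The astrocyte list itself was mixed. Of 23 measured members 7 were lower, 3 higher and 13 neither, with a median log2 ratio of −0.25 at percentile 32.8. Gfap, Aqp4 and Clu, the secreted chaperone clusterin, were lower, at log2 ratios of −5.76, −4.57 and −3.18. Slc6a11, a GABA transporter, and S100b, a calcium-binding protein of astrocytes, were higher, at 4.04 and 2.79. Genes shared by glia and their progenitors were also mixed, with 6 lower and 3 higher of 15 and a median of 0.74 at percentile 99.3. Id3 and Id1, inhibitors of differentiation downstream of BMP signals, were 38.4-fold (36.6 to 40.2) and 30.0-fold (27.6 to 32.7) lower. Fabp7, the brain lipid-binding protein of radial glia, was 5.60-fold higher (5.56 to 5.64).

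Some progenitor and growth factor response genes were higher in MIM-treated astrocytes. Of 17 neural progenitor genes 5 were higher, 1 lower and 11 neither, with a median log2 ratio of 0.26 at percentile 98.4. That median was −0.00 when each cell weighed the same, so the list as a whole had no firm direction. Hes5, a Notch target that holds progenitors undifferentiated, was 43.7-fold higher (34.5 to 56.2). Egfr, the EGF receptor, was 10.1-fold higher (8.89 to 11.6). Sox2 stood at 148 CPM (145 to 152) against 168 CPM (164 to 171), and Nes, encoding nestin, at 50.9 CPM (49.0 to 52.9) against 62.6 CPM (60.5 to 64.8). Both of these differences were under 2-fold. Of 15 genes of FGF and MAPK feedback 9 were higher and 0 lower, with a median of 1.12 at percentile 100. Only 2 of these 9 also reached 50 CPM. The FGF-induced transcription factor gene Etv1 was 12.2-fold higher (10.8 to 13.96), and Spry2, a feedback inhibitor of receptor tyrosine kinases, 6.88-fold higher (6.60 to 7.17). Of 10 oligodendrocyte lineage genes 5 were higher and 1 lower, with a median of 0.90 at percentile 99.96. Olig2, the lineage transcription factor, was 21.6-fold higher (18.5 to 25.4).

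One-carbon genes did not differ as a group. Of 26 measured genes of the one-carbon and methionine cycle 5 were higher, 3 lower and 18 neither, with a median log2 ratio of 0.04 at percentile 90.2. Without Malat1 in the totals the median was −0.02. Psph, the last enzyme of serine synthesis, was 2.96-fold higher (2.87 to 3.06). Mat2a, which makes S-adenosylmethionine, had a log2 ratio of −1.17. Of 33 chromatin methylation genes 3 were higher and 2 lower, with a median of 0.21 at percentile 99.7. Ezh2, the histone H3 methyltransferase of Polycomb, was 5.06-fold higher (4.69 to 5.46), and Setd7, a lysine methyltransferase, had a log2 ratio of −2.01. Of the 20 pluripotency genes only 6 had 20 UMIs or more over both libraries. Of these 0 were higher and 3 lower, and their median was −1.24 at percentile 0.15. Tfcp2l1 stood at 0.0786 CPM against 21.7 CPM, and Pou5f1, encoding Oct4, was at or below 0.0988 CPM in both libraries.

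**Figure D1:**
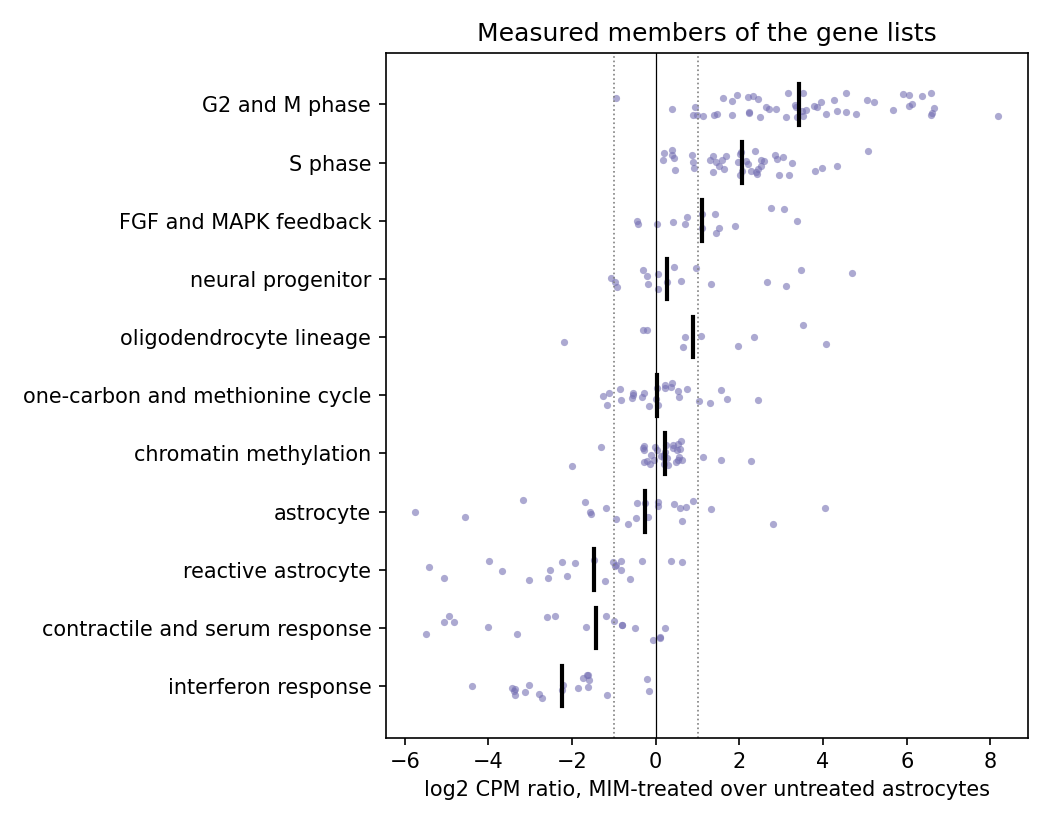
Log2 CPM ratio of MIM-treated over untreated astrocytes (x axis) for each measured member of 11 gene lists (1 point per gene; vertical position within a list has no meaning); thick bars mark list medians and dotted lines a log2 ratio of −1 and 1. The G2 and M phase and S phase lists lie to the right, with medians of 3.44 and 2.06, and the interferon response list to the left, with a median of −2.23.

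The second comparison set the starting state against the reference state, astrocytes against neural stem cells. Some astrocyte markers were far higher in astrocytes. Gfap was 235-fold higher (146.5 to 403), and Clu stood at 4070.4 CPM (4052.8 to 4088) against 16.1 CPM (14.2 to 18.3). Some progenitor and cell division genes were far lower. Hes5 was 141-fold lower (111 to 182), at 1.38 CPM against 195 CPM. Among 3192 genes at 50 CPM or more, 997 were higher and 732 lower, 57.7% higher. Without Malat1, a nuclear noncoding RNA that took 26.9% of UMIs in neural stem cells and 13.7% in astrocytes, 867 were higher and 1078 lower, 44.6% higher. That scaling moved the median log2 ratio by −0.24, and leaving mitochondrial and ribosomal protein genes out of the totals moved it by −0.13, while TMM scaling moved it by 0.16.

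The 13 genes highest in astrocytes relative to neural stem cells were Hspb8, Serpinf1, Clu, Ogn, Fbxo2, Lbp, Cd59a, Ass1, Cryab, Elobl, Plscr2, Gfap and Omd. Serpinf1 had 2 UMIs in neural stem cells and 51424 in astrocytes, a ratio of 7465-fold with a counting interval from 2066 to 61643. Ogn, a small proteoglycan of bone and connective tissue, had 0 UMIs in neural stem cells and was at least 923.5-fold higher against the same floor. Cryab, alpha-B crystallin, was 135-fold higher (124.5 to 147). With C530008M17Rik (log2 ratio −5.70) and the ribosomal protein gene Rps28 (−5.58) left out, the 13 lowest were Prc1, Pclaf, Hes5, Grm5, Fbln2, Nrgn, Ppp1r16b, Dpp6, Slc6a11, Ube2c, Trib2, Abhd2 and Cenpf. Grm5, a metabotropic glutamate receptor, was 173-fold lower (124 to 249), and Slc6a11 214-fold lower (133 to 369). Prc1 was 247-fold lower (182 to 345).

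Gene groups separated the same pair of libraries. Of 18 neural progenitor genes 11 were lower and 0 higher in astrocytes, with a median log2 ratio of −1.39 at percentile 0.020. Of 23 astrocyte genes 11 were higher and 4 lower, with a median of 0.82 at percentile 98.9. Of 20 interferon response genes 18 were higher and 0 lower, and the median was 3.70. Of 21 reactive astrocyte genes 15 were higher and 1 lower, with a median of 2.41. Of 15 FGF and MAPK feedback genes 13 were lower and 0 higher, with a median of −2.48. Of 52 G2 and M phase genes 44 were lower and 1 higher, with a median of −2.40, and of 40 S phase genes 26 were lower and 1 higher, with a median of −1.49. Of 33 chromatin methylation genes 24 were lower and 0 higher, with a median of −1.52. Kdm6b, a histone H3 lysine 27 demethylase, had a log2 ratio of −3.95. With Malat1 at 26.9% of UMIs in neural stem cells and 13.7% in astrocytes, a larger nuclear RNA share in neural stem cells was not separated from expression for this list. Of 11 oligodendrocyte lineage genes 9 were lower and 0 higher, with a median of −3.38. The one-carbon and methionine cycle list had 4 of 26 higher and 2 lower, with a median of 0.16 that turned to −0.07 under another scaling.

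Transcripts of cytosolic ribosomal proteins took 2.87% of UMIs in astrocytes, 11.6% in neural stem cells and 8.40% in MIM-treated astrocytes. Over 81 such genes the median log2 ratio of astrocytes over neural stem cells was −2.02, and it lay between −2.26 and −1.86 under all 4 scalings tried. The median of MIM-treated over untreated astrocytes was 1.65, between 1.58 and 1.89.

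The third comparison asked how close MIM-treated astrocytes lay to neural stem cells. Clu was 27.7-fold higher (24.4 to 31.6) in MIM-treated astrocytes than in neural stem cells, and Nupr1, a stress-induced transcriptional regulator, 102-fold higher (51.5 to 236). Egr1, an immediate early transcription factor, was 79.3-fold lower (59.0 to 109), and Igf1r, the IGF1 receptor, 15.2-fold lower (13.05 to 17.9). Among 2830 genes at 50 CPM or more, 575 were higher and 458 lower, 55.7% higher. This balance depended on scaling. TMM gave 1121 higher and 242 lower (82.3% higher) and moved the median log2 ratio by 0.40. Totals without Malat1 gave 329 higher and 834 lower (28.3% higher) and moved it by −0.31.

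Leaving out 1500015O10Rik, a gene with a clone name (log2 ratio 4.50), the 13 genes highest in MIM-treated astrocytes relative to neural stem cells were Nupr1, Clu, Ifitm3, Chchd10, Tmem176a, S100a16, Rida, Tk1, Anxa5, Dcxr, Pbk, Hist1h4i and Hist1h2bc. Ifitm3, an antiviral membrane protein with close paralogs, was 32.1-fold higher (22.3 to 48.0). The values of Ifitm3 and of both histone genes are uncertain, since near-identical copies can share their reads. With the gene model CT025619.1 left out (log2 ratio −3.51), the 13 lowest were Egr1, Rnase1, Calcrl, Ppp1r16b, Anks1b, Mfge8, Chd3, Igf1r, Kdm6b, F2r, Gigyf1, Fbln2 and Khsrp. Mfge8, a secreted bridging protein of phagocytosis, was 14.3-fold lower (13.5 to 15.2), and Kdm6b was 10.4-fold lower (9.81 to 11.0). Of 18 neural progenitor genes 10 were lower and 0 higher in MIM-treated astrocytes than in neural stem cells, with a median log2 ratio of −1.21 at percentile 0. Of 24 astrocyte genes 9 were higher and 4 lower, with a median of 0.53 at percentile 99.1. Of 52 G2 and M phase genes 30 were higher and 2 lower, with a median of 1.15 at percentile 100, and of 42 S phase genes 17 were higher and 0 lower, with a median of 0.89 at percentile 100. Of 33 chromatin methylation genes 21 were lower and 0 higher, with a median of −1.26 at percentile 0. The nuclear RNA Malat1 took 26.9% of UMIs in neural stem cells against 9.44% here and 13.7% in astrocytes, so for this list a larger share of nuclear RNA in neural stem cells was not separated from a difference in expression. Of 18 interferon response genes 10 were higher and 0 lower (1.06, percentile 100), and of 15 reactive astrocyte genes 6 were higher and 0 lower (0.77, percentile 100). Of 15 FGF and MAPK feedback genes 8 were lower and 0 higher (−1.04, percentile 0.770), and of 11 oligodendrocyte lineage genes 9 were lower and 0 higher (−1.41, percentile 0.04). Mki67 stood at 18.1 CPM (16.9 to 19.3) in MIM-treated astrocytes against 17.8 CPM (15.7 to 20.1). Of 6 sex-linked genes 3 were lower and 0 higher than in neural stem cells, with a median of −0.89, and in untreated astrocytes too 3 were lower and 0 higher (−0.86). Xist, the RNA that silences an X chromosome, stood at 224 CPM in neural stem cells, 24.5 in astrocytes and 35.2 in MIM-treated astrocytes. The Y-linked genes went both ways, with Eif2s3y at 12.7, 16.8 and 19.1 CPM, Ddx3y at 8.37, 11.96 and 9.88, Uty at 10.3, 4.07 and 3.73, and Kdm5d at 4.56, 2.77 and 2.91. The labels give no sex, so a different mix of sexes in the neural stem cell culture stays open as a limit of both comparisons with it. The median of the ribosomal protein genes was −0.28 and turned to 0.12 under another scaling.

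**Figure D2:**
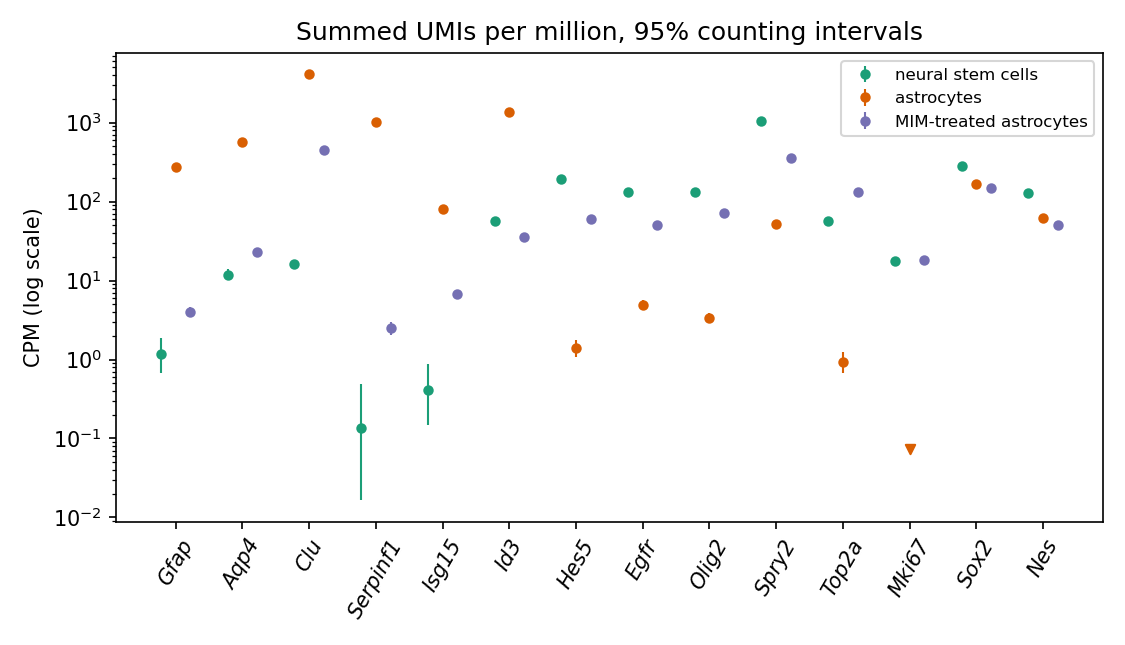
Summed level (CPM, log y axis) of 14 genes (x axis) in the 3 libraries, with 95% counting intervals; the triangle is the upper limit of the interval for Mki67 in astrocytes, which had 0 UMIs. Gfap stands at 272 CPM in astrocytes against 4.05 CPM in MIM-treated astrocytes and 1.16 CPM in neural stem cells, while Sox2 stands at 168, 148 and 278.5 CPM in the same order.

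Genes that separated astrocytes from neural stem cells mostly lay on the neural stem cell side in MIM-treated astrocytes. Of the 1729 genes counted as higher or lower in astrocytes, 1577 had a MIM-treated level on the neural stem cell side of the astrocyte level, 91.2% (89.8 to 92.5). Of the same genes 839, or 48.5%, were at least midway to the neural stem cell level on the log2 scale, and 10.3% lay beyond it. Both differences share the astrocyte library, and simulated MIM-treated counts with no effect gave a median of 50.7% and at most 53.5%. Profiles with shuffled genes gave a mean of 72.4%, between 70.3% and 74.4% over 100 shuffles, so much of the distance from 50% arises without any relation between the libraries. No shuffled value was computed for the 48.5%. Shuffled profiles had a slope of 0.494, about midway as well, so the 48.5% alone shows no shift. With the astrocyte cells split into 2 equal sets, 1 for each difference, the share was 91.1%. Splitting removes shared counting error and leaves in whatever is peculiar to this 1 astrocyte culture.

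The genes counted in both comparisons overlapped in opposite directions. Among 2768 genes at 50 CPM or more in both, 441 were higher in astrocytes than in neural stem cells and lower in MIM-treated astrocytes, where 183 would overlap for independent lists. Another 256 were lower in astrocytes and higher in MIM-treated astrocytes, against 53.0. Sec11c, a signal peptidase subunit, was the 1 gene higher at both steps, against 129 for independent lists. Ncan, the brain proteoglycan neurocan, was the 1 gene lower at both, against 75.1. These 2 genes were named after their values were seen. The independent-list values leave out the shared astrocyte library, so part of each excess may come from it. The threshold adds to this. Of 732 genes lower in astrocytes, only 409 were among those 2768. A gene under 50 CPM in astrocytes entered only with at least 50 CPM in MIM-treated astrocytes, thus above the astrocyte level. The 256 genes and the 1 gene lower at both are partly set by that filter.

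Across 3319 genes the log2 ratio of MIM-treated over untreated astrocytes had a slope of 0.604 (0.581 to 0.628) on that of neural stem cells over astrocytes, with r = 0.808. Genes are not independent replicates. The covariance was 2.06, against 0.000821 simulated with no effect, and the slope was 0.6035 with split astrocyte cells. Profiles with shuffled genes, which share nothing but the common library, also gave a slope of 0.494 and r = 0.488, so the slope alone says little. The pairing that shares the MIM-treated library is more telling. The differences of astrocytes and of neural stem cells from MIM-treated astrocytes had r = −0.103 (−0.149 to −0.0603), where shuffled profiles gave 0.515. Log CPM correlated across genes at 0.809 between MIM-treated astrocytes and neural stem cells, 0.691 between MIM-treated and untreated astrocytes, and 0.433 between astrocytes and neural stem cells.

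**Figure D3:**
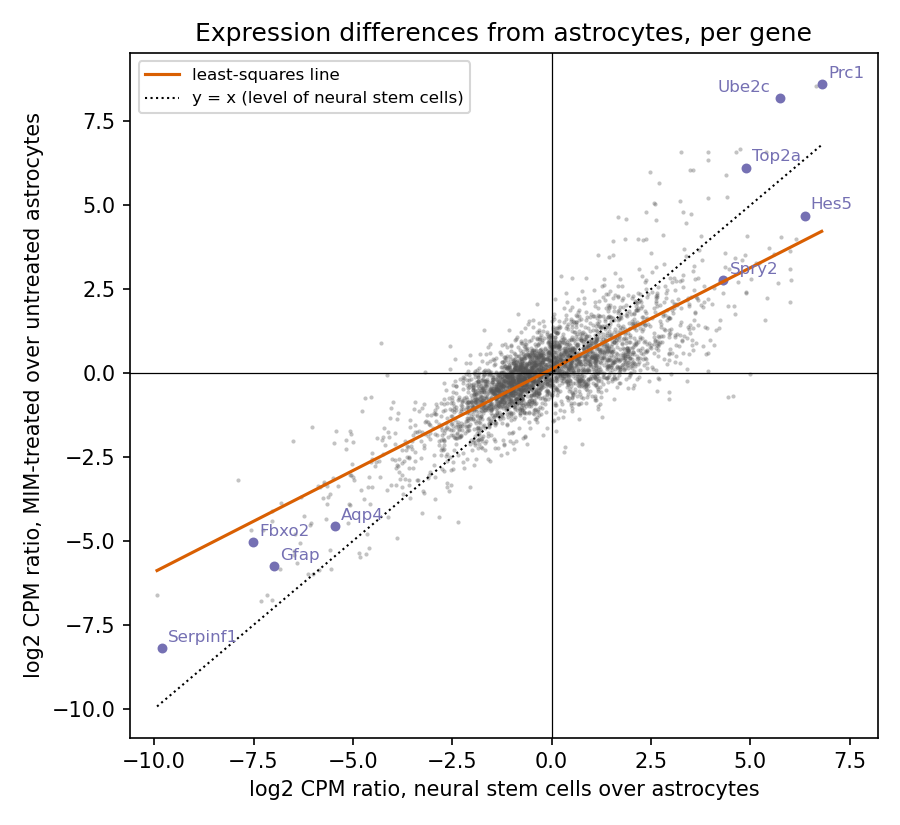
Each point is 1 of 3319 genes, with the log2 CPM ratio of neural stem cells over astrocytes on the x axis and of MIM-treated over untreated astrocytes on the y axis. The solid line is the least-squares line with a slope of 0.604 and the dotted line marks equality with neural stem cells; Prc1, Ube2c and Top2a lie above the dotted line, while Hes5 and Spry2 lie between it and 0.

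Single MIM-treated cells mostly scored between the cells of both reference libraries. Each cell was thinned to 1000 UMIs and set against profiles from a random 50% of neural stem cells and of astrocytes. All 3844 held-out neural stem cells and 0 of 4734 held-out astrocytes (exact upper limit 0.0779%) were nearer to neural stem cells. Of 13991 MIM-treated cells 10384 were nearer to neural stem cells, 74.2% (73.5 to 74.9). The median difference of correlations was 0.0474 in MIM-treated cells, against 0.236 in neural stem cells and −0.233 in astrocytes. Cells equally unlike both profiles would also score near 0, so this difference alone does not show an intermediate state. The thinning left out 1457 neural stem cells, 351 astrocytes and 973 MIM-treated cells with fewer UMIs.

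**Figure D4:**
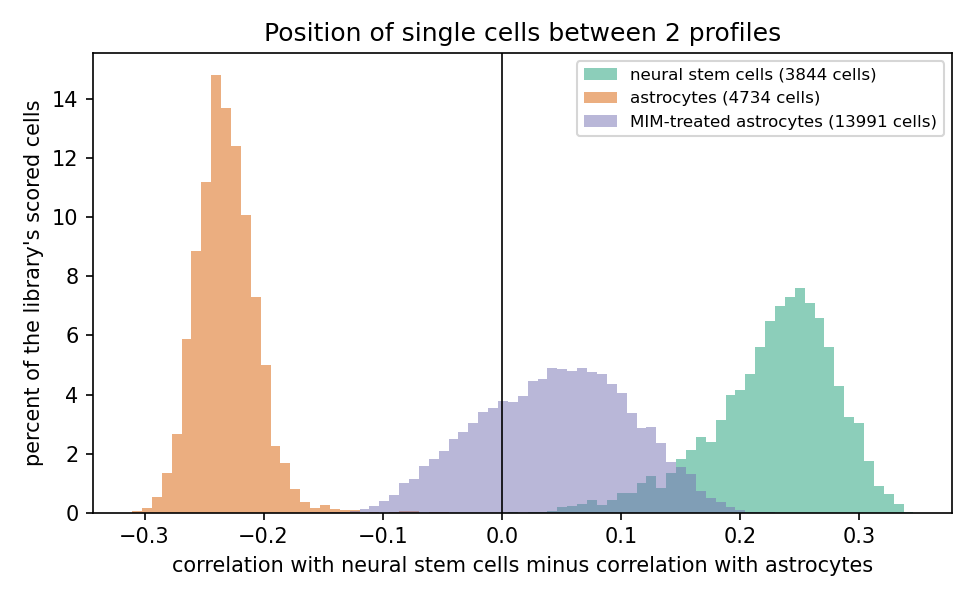
Distribution over cells of the correlation with the neural stem cell profile minus that with the astrocyte profile (x axis), as a percent of each library's scored cells (y axis), at 1000 UMIs per cell. Medians are 0.236 for neural stem cells, −0.233 for astrocytes and 0.0474 for MIM-treated astrocytes, 74.2% of which lie above 0.

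Shares of cells with a UMI of a marker depended on depth, and for Sox2, Nes, Tubb3, Mki67 and Pou5f1 the order of the libraries differed between depths. At 1000 UMIs per cell, Gfap was seen in 17.9% of astrocytes (17.2 to 18.7) and 0.279% of MIM-treated cells (0.198 to 0.381), beside 0.104% (0.0449 to 0.205) in neural stem cells, which should lack it. Unthinned, these shares were 46.4%, 1.20% and 0.175%. Top2a was seen in 0.0528% of astrocytes (0.0172 to 0.123), 8.28% of MIM-treated cells and 2.91% of neural stem cells at 1000 UMIs, and in 0.469%, 18.9% and 4.39% unthinned. Mki67 was seen in 0 of 9818 astrocytes unthinned, which by the floor of 3 counts allows up to 0.0306% of cells with a UMI and says nothing of cells that express it without one. It was seen in 5.23% of MIM-treated cells and 2.43% of neural stem cells. At 1000 UMIs it was seen in 1.49% of MIM-treated cells and 1.20% of neural stem cells, and at 2000 UMIs in 3.28% of 11354 and 4.95% of 1615 cells deep enough, the reverse order. At 2000 UMIs Top2a was seen in 15.5% of MIM-treated cells and 13.7% of neural stem cells. Aqp4 was seen in 38.7%, 2.13% and 1.27% of astrocytes, MIM-treated cells and neural stem cells at 1000 UMIs, and in 76.4%, 6.94% and 1.80% unthinned. Sox2 was seen in 15.6%, 13.8% and 23.4% of these libraries at 1000 UMIs and in 54.0%, 36.8% and 32.2% unthinned. Nes was seen in 6.12%, 5.22% and 11.1% at 1000 UMIs and in 22.97%, 14.97% and 17.0% unthinned. Tubb3, a neuronal tubulin, was seen in 0.908%, 0.486% and 1.25% at 1000 UMIs and in 4.39%, 1.04% and 1.89% unthinned. Pou5f1 was at most 0.131% in any library unthinned and at most 0.0520% at 1000 UMIs.

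Clustering all cells together gave 8 clusters, each with over 90% of its cells from 1 library, so a cluster here may be a library and not a type. Of MIM-treated cells 36.6% lay in an astrocyte-like cluster led by Slc4a4, S100b, Sparcl1, Apoe and Glul among its markers. Gfap and Aqp4 stood at only 7.37 and 34.7 CPM there, against 270 and 568 CPM in the main cluster of untreated astrocytes. S100b, at 115 CPM, was about as high in the oligodendrocyte lineage-like (105) and shallow (123) MIM clusters, so this name too is limited. Another 29.9% lay in an oligodendrocyte lineage-like cluster with Lhfpl3, Olig1 and Olig2. Pdgfra, the receptor that marks oligodendrocyte precursors, stood at only 3.13 CPM there, and Sox10, a transcription factor of the same lineage, at 0.0589 CPM in the whole MIM-treated library, so that name rests on few markers. A further 26.9% lay in an unnamed cluster with 24 cell cycle genes among its top 50. The remaining 6.58% lay in a shallow unnamed cluster. Of neural stem cells 68.7% lay in an unnamed cluster with Hes5 and Egfr, and 30.7% in an oligodendrocyte lineage-like cluster with Lhfpl3, Pdgfra, Olig2 and Sox10, where Pdgfra stood at 63.2 CPM. Of astrocytes 95.1% lay in an astrocyte-like cluster with Aqp4, Gfap and Clu, and 4.88% in a shallow unnamed cluster.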

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

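Of 179 alternative values 154 kept the result, 23 moved it and 2 reversed it. A count was kept within 1.5 times its value, and a share, slope or median within its 95% interval, so kept counts of higher and lower genes could still turn their balance. These leave out the marker shares, of whose 48 values at other depths 38 moved. The alternatives on Malat1, Scrublet scores and shallow clusters were chosen after seeing the data. The Scrublet alternative fixed beforehand called 0 cells, and no microglia, fibroblast, endothelial or ependymal cluster was found to leave out, so neither gave a value. Except where said, the cause was not tested.

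The 2 reversals were small. The median of the neural progenitor list in MIM-treated over untreated astrocytes was −0.004208 as a mean over cells. The median of the one-carbon and methionine cycle list was −0.02145 without Malat1.

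TMM gave 1121 genes higher and 242 lower in MIM-treated astrocytes than in neural stem cells, and 84.59% toward neural stem cells. Totals without Malat1 gave 329 higher and 834 lower, and 89.36% toward. Totals without mitochondrial and ribosomal protein genes gave 500 genes higher and 474 lower in MIM-treated than in untreated astrocytes.

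A pseudocount of 10 CPM gave 92.75% toward, with medians of 0.8008 for S phase and 1.425 for G2 and M phase. A larger pseudocount shrinks ratios of genes near 0 by construction.

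At 20 CPM, 978 genes were lower in MIM-treated than in untreated astrocytes, 1591 were higher and 1386 lower in astrocytes than in neural stem cells, 774 were higher and 1043 lower in MIM-treated astrocytes than in neural stem cells, and 89.18% lay toward. At 100 CPM 307 genes were higher and 264 lower in MIM-treated than in untreated astrocytes, 604 higher and 413 lower in astrocytes than in neural stem cells, 203 lower in MIM-treated astrocytes than in neural stem cells, and the slope was 0.635. These counts follow from the number of genes admitted.

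Without both cycle lists the slope was 0.5806. Of MIM-treated cells 81.46% were nearer to neural stem cells at 2000 UMIs and 66.91% by Spearman correlation. Resolution 0.25 gave 5 clusters.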

Other observations

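Of the gene lists not described above, several were lower in MIM-treated than in untreated astrocytes. Of 18 extracellular matrix genes 10 were lower and 1 higher, with a median log2 ratio of −1.09 (percentile 0). Of 9 ependymal genes 7 were lower and 0 higher (−1.65, percentile 0.01), and of 6 fibroblast genes 4 were lower and 0 higher (−1.08, percentile 0.990). Of 16 immediate early and heat shock genes 6 were lower and 1 higher (−0.81, percentile 0.480), and of 18 hypoxia and glycolysis genes 3 were lower and 0 higher (−0.68, percentile 0.160). Of 11 neuron genes 4 were lower and 1 higher (−0.70, percentile 4.255), while of 6 intermediate progenitor genes 3 were higher and 0 lower (1.02, percentile 99.88). Among the higher and lower genes of the ependymal, fibroblast, neuron and intermediate progenitor lists, 0 also reached 50 CPM. The 6 sex-linked genes had 0 higher and 0 lower, with a median of −0.01 that turned to 0.16 under another scaling.

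Among metabolic lists, of 17 polyamine genes 3 were lower and 2 higher (−0.70, percentile 1.835), and of 19 cysteine and glutathione genes 9 were lower and 1 higher (−0.29, percentile 25.7). Of 21 amino-acid response genes 3 were higher and 3 lower (0.51, percentile 99.98), and of 24 cholesterol synthesis genes 2 were higher and 2 lower, with a median of 0.01 (percentile 90.4) that turned to −0.05 without Malat1. Of 14 cell cycle arrest genes 5 were lower and 0 higher (−0.43, percentile 22.5). Of 5 metallothionein genes 1 was lower and 0 higher (−0.72, percentile 3.94), and of 11 epithelial-mesenchymal regulators 2 were higher and 2 lower (−0.35, percentile 28.3). The microglia list and the endothelial and mural list had 2 measured members each, too few for a median.

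The tests of mixing and unrelated profiles, the tests of copies, depth and Malat1 loss against neural stem cells, the recurrence test, and the correlation for the non-cycling cluster were chosen only after the results were seen. The limit of the copies test was also moved after its value was seen, and at the limit first set it decided nothing. The mixing test on genes higher in astrocytes was added once that on genes lower in astrocytes had left mixing open.

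MIM-treated astrocytes lay toward neural stem cells, and cycling cells alone did not account for it: the slope was 0.4898 with the non-cycling MIM cluster and without cycle genes, although unrelated profiles give 0.494, and the correlation that decides, sharing that cluster, was −0.161 (−0.203 to −0.120). Neural stem cells mixed into the library stay open by the summed levels of genes lower in astrocytes. Their median needs a share of 28.5% (24.95 to 32.3). Only 3.825% of 732 such genes lay more than 2-fold below the level that share would bring, by the upper 95% limit of their ratio. Genes nearer to that level were not counted as too low. Quartiles of single cells do not settle this. The upper quartile of the difference of correlations was 0.0911 in MIM-treated cells, under the lower quartile of 0.199 in held-out neural stem cells. At a share of 28.5%, some of it under that lower quartile, the upper quartile of a mixed library could also lie below 0.199. The 28.5% is moreover a share of UMIs and not of cells. The 997 genes higher in astrocytes need 66.33% (63.7 to 70.3), so mixing alone cannot account for both sets. The correlation sharing the whole MIM-treated library was −0.1027, against 0.515 for unrelated profiles. Whatever is peculiar to the 1 astrocyte culture, some mixing, and serum, FGF2 and metabolites as separate causes, stay open.

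Ribosomal protein transcripts were lower in the astrocyte library, but not evenly. The log2 ratio of astrocytes over neural stem cells ran from −5.585 for Rps28 to 1.272 for Rpl7l1. A technical cause in this 1 library that acts on some transcripts more than on others was not tested. The 8 genes with no shared 50-mer near the transcript end had a median of −1.846 (−4.68 to −0.862), which at the moved limit left out reads lost to copies as the cause. At 1000 to 2000 UMIs per cell the median neural stem cell share was 4.41 times the astrocyte share, so depth alone did not account for it there. This set 6076 neural stem cells against only 326 astrocytes, which were shallow for a library with a median of 5089 UMIs. Loss of cytoplasmic RNA would raise the Malat1 share, which was 0.5078 times that of neural stem cells. This ratio cannot decide, since neural stem cells may themselves hold a larger share of nuclear RNA or express more Malat1. At like Malat1 share the MIM-treated share was 2.719 times that of astrocytes.

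The difference between the oligodendrocyte lineage-like cluster and the main other cluster recurred in neural stem cells and MIM-treated astrocytes. Across 3319 genes both contrasts had r = 0.6052 (0.5675 to 0.642), or 0.577 without class markers. Both oligodendrocyte lineage-like clusters were picked by the same marker list from the same clustering, so part of this correlation is built in. No other pair of clusters was set beside it. Of 92 genes past log2 1 in both, 85 had the same direction, among them Lhfpl3 (2.73 and 3.04) and Aldoc (−1.96 and −1.94). The other 7 were all cell division genes, such as Prc1 (−3.45 and 1.11). Shallow against deep cells of 1 MIM cluster correlated with the neural stem cell contrast at −0.07258, so depth did not account for it.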
